A study of Mus musculus with 2 samples.

How the data were processed

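The starting point was the filtered count matrix that the authors deposited for each library, with barcodes and genes as listed there and UMI counts as values. Per the file headers the counts came from Cell Ranger 3.1.0, while the submitters' processing notes give Cell Ranger 3.0.2 and Seurat 3.1.1 with the mouse genome build mm10, and the disagreement was left open. Per the labels the cells were captured with 10x Chromium 3' chemistry after cold protease dissociation, removal of dead cells and lysis of red cells. No upstream step was rerun. Both matrices held the same 31053 genes, among them 36 duplicated symbols, which were kept apart by Ensembl identifier. Gene positions for mm10, which is GRCm38, were taken from GENCODE vM21.

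Barcodes with at least 500 UMIs, at least 200 genes and less than 50% mitochondrial UMIs were kept, and Scrublet was run on each library. Of 6938 wild type and 7950 knockout barcodes, 4371 and 7236 passed, 54 (1.24%) and 170 (2.35%) of these were removed as doublets, and 4317 and 7066 remained. At 50% or more mitochondrial UMIs stood 2564 wild type barcodes (37.0%) and 706 knockout barcodes (8.88%). Kept cells held 42468386 and 79060495 UMIs. Median UMIs per cell in wild type and knockout were 8050.5 and 7922 in proximal tubule-like, 8798 and 8968 in thick ascending limb-like, 7047 and 8973 in distal convoluted tubule-like, 11055 and 8476 in intercalated-like and 2339 and 2703.5 in endothelium-like cells.

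Counts were log-normalised to 10000 per cell over genes found in at least 10 cells, and 2000 variable genes per library, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 with seed 0 gave 30 clusters. The libraries were clustered together without integration. Clusters were named from markers of 25 cell types, and a name needed at least 3 markers that reached 50 CPM, 20 UMIs and 2-fold over the median of the other clusters. The named type also had to hold more of the 10 leading genes than any other type, or the cluster stayed unnamed, as did clusters with markers of 2 types. This naming rule was written after the clusters had been seen, while markers, gene lists and the rule for naming genes were chosen before the data were examined. Clusters 10, 12, 25 and 28 stayed unnamed. The injured tubule markers share genes with the tubular injury list, and Lcn2 and Spp1 are on both that list and the list of secreted factors.

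A class was compared where each library gave at least 100 cells, which left 6 classes. The immune-like and mural-like classes and injured tubule-like cells had fewer in wild type and are reported as shares and as sources of secreted factors, and the tubular epithelium as a whole was compared for Kif3a only, since its makeup differed so much between libraries. UMIs were summed over the cells of a class and divided by the class total. Log2 ratios are knockout over wild type with 0.5 UMIs added to each sum, with an interval from the exact conditional test of 2 Poisson sums. Sums carry exact Poisson intervals and shares exact Clopper-Pearson intervals. Where a library had no UMI, the bound sets the other library against 3 counts. No gene was called as changed and no p-value was computed, since 1 library per genotype gives no replicate variation.

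Genes named in a class were the 10 highest and the 10 lowest log2 ratios among genes with at least 50 CPM and 50 UMIs in the higher library, an interval that leaves out 0, and a level of at least 0.5 times that of all cells of the higher library, to leave out free RNA. Mitochondrial, ribosomal, haemoglobin and predicted genes and the naming markers were left out. Named genes that lead a cluster of their class were left out of the report as well, since the names had been built on such clusters (Wfdc15b in both distal classes, Inmt and Dnase1 in proximal tubule), and in lists the same held for Slc13a1 and Acsm2 in proximal tubule and Lcn2 and the marker Ptger3 in thick ascending limb-like and Lcn2 in principal-like cells.

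There were 19 gene lists: procachectic and muscle-wasting secreted factors, activin and TGF-beta antagonists, tubular injury, proximal tubule transport, distal nephron transport, fatty acid oxidation, oxidative phosphorylation from the nucleus, glycolysis, extracellular matrix and fibrosis, primary cilium, hedgehog and Wnt targets, chemokines and inflammatory cytokines, interferon response, antigen presentation, macrophage remodelling, cell cycle, p53 response, dissociation stress, and endothelial activation and glomerular endothelium. A member counted with at least 20 UMIs over both libraries. The list median was placed among 10000 random lists of the same size drawn from 20 bins of expression, and members were counted as higher or lower at 1.5-fold relative to the median gene, a step added after the data had been seen. The median gene was taken over genes with at least 100 UMIs. Up to 4 members per list, those with the largest log2 ratios, could be named, and every secreted factor. With members lacking UMIs in wild type set at their bound, the injury median before subtraction of the median gene was 4.01 in thick ascending limb against 4.66, 2.89 in distal convoluted tubule against 3.19, 1.98 in principal against 1.99 and 2.61 in intercalated against 2.79. The same step gave 3.45 against 3.87 for secreted factors and 3.50 against 4.36 for matrix in thick ascending limb, 2.63 against 3.19 for secreted factors and 2.78 against 4.95 for chemokines in distal convoluted tubule, 0.83 against 1.24 for p53 in principal and 3.69 against 4.93 for interferon in intercalated-like cells. Which 51 of the pairs of list and class are reported, and which of these count as main results, was settled after the medians and a first table of alternatives had been seen. Of the 51, 44 lie outside the central 95% of random lists. Pairs given only to compare classes are not among the 51.

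Free RNA was estimated per class from genes that mark other classes, an estimator whose details were set after the data had been seen, and it came to 1.70% and 3.08% of UMIs in proximal tubule-like, 1.75% and 2.38% in thick ascending limb-like, 3.42% and 3.52% in distal convoluted tubule-like, 2.17% and 3.23% in principal-like and 2.97% and 5.87% in intercalated-like cells.

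Alternatives chosen before the data were examined were a mitochondrial limit of 25%, at least 1000 UMIs per cell, doublets kept, libraries clustered separately, Leiden resolutions 0.5 and 2, cells thinned to 1000 UMIs, trimmed-mean and median-of-ratios scaling, totals without mitochondrial and the 50 most abundant genes, a mean over cells, free RNA subtracted, list members with at least 1 or at least 100 UMIs, and named genes with at least 200 UMIs. Added after seeing the data were proximal tubule-like cells against wild type clusters 0 and 9 only and against clusters 2 and 13 only, cells at or under the wild type median share of the dissociation list, tubule cells drawn in equal number per library from each 5-point bin of mitochondrial percent, all barcodes scored by immune markers before the filter, secreted factors without cluster 28, and lists of male-biased and female-biased proximal tubule genes.

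The method was tested on simulated data in which both libraries of a class were drawn by Poisson sampling from the pooled profile at the observed depths. In each class 200 genes were changed between 1.5-fold and 8-fold, and 200 lists of 20 genes were left unchanged. Such draws hold counting error only, not variation between mice. Intervals covered the true ratio for 95.7% of genes in proximal tubule-like and 96.2% in intercalated-like cells, the lowest and highest of the classes. Genes changed 2-fold were recovered in 98% of cases in proximal tubule, 100.0% in thick ascending limb, 90% in distal convoluted tubule, 70% in principal, 96% in intercalated and 92% in endothelium-like cells. Unchanged lists fell outside the central 95% in 2% of cases in proximal tubule and in 9% in intercalated-like cells, so a list just past that limit in the latter class carries little weight.

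Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, anndata 0.12.19, python-igraph 0.11.9 and matplotlib 3.10.9, and in R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0, the last 2 for scaling factors only.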

Results

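Single-cell 3' RNA profiles were collected from the kidneys of 5-week-old mice, with 1 wild type library and 1 with tubule-specific deletion of Kif3a, a motor protein needed to build the primary cilium. Per the series title, the data served to ask how procachectic factors of chronic kidney disease relate to muscle wasting, so the secreted factors linked to wasting were followed through every cell class. After filtering, 4317 wild type and 7066 knockout cells remained, with medians of 7771 and 7799 UMIs per cell. The wild type cells held a median of 26.8% mitochondrial UMIs and the knockout cells 7.54%. With 1 library per genotype, no difference reported here has a replicate check, and all intervals are 95% intervals that cover counting error only. Levels are UMIs in CPM of a class or library and are given for wild type first and knockout second.

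Kif3a itself was not lower in the knockout library as a whole, at 10.3 (9.37 to 11.3) CPM in wild type and 12.2 (11.5 to 13.01) in knockout over all kept cells, and at 9.69 and 11.8 over the tubular epithelium. It was lower in principal-like cells, at 24.0 and 11.0 CPM (log2 ratio -1.15, -1.74 to -0.46), and in intercalated-like cells, at 15.3 and 8.81 (log2 ratio -0.80, -1.46 to -0.15). Proximal tubule-like cells had more of it, at 8.22 and 14.5 (log2 ratio 0.82, 0.52 to 1.12), while thick ascending limb-like cells stood near equality at 11.6 and 11.1. The direction over the whole tubule turned with scaling, from a log2 ratio of 0.28 to -0.27 under both trimmed-mean and median-of-ratios factors, to -0.07 with totals that left out mitochondrial and the most abundant genes, and to -0.09 under a mitochondrial limit of 25%. The deleted part of the gene was not given, and a 3' tag can lie outside it, so these levels check neither the deletion nor the labels.

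The knockout library held far fewer proximal tubule-like cells and far more principal-like, injured tubule-like and immune-like cells. Cells like proximal tubule made up 68.2% (66.8 to 69.6) of the wild type library and 14.4% (13.6 to 15.2) of the knockout library. Cells like those of the connecting tubule and the principal cells of the collecting duct, called principal-like here, made up 3.22% (2.71 to 3.79) and 15.8% (15.0 to 16.7). Injured tubule-like cells, which carry markers of damaged or dedifferentiated tubule, were 1 cell in wild type and 829 in knockout, or 11.7% (11.0 to 12.5). They formed 1 cluster, number 24, whose leading genes were Lcn2, other injury genes such as Krt18, and the collecting duct genes Aqp2, Fxyd4 and Hsd11b2. A mitochondrial limit of 25% left 404 of them in knockout, or 6.44%. No cluster took that name with at least 1000 UMIs per cell, at clustering resolutions 0.5 and 2 or after thinning. Thick ascending limb-like cells were near level at 7.88% and 8.11%, as were distal convoluted tubule-like cells at 5.03% and 4.93% and intercalated-like cells at 6.63% and 6.35%. Among the distal convoluted tubule-like cells, however, cluster 3 held 159 wild type cells and 1 knockout cell, and cluster 16 held 58 and 347. Endothelium-like cells were 3.59% (3.06 to 4.19) and 6.71% (6.14 to 7.32), podocyte-like cells 0.417% and 0.425%, urothelium-like cells 0.116% and 1.17%, and mural-like cells, the class that includes mesangial and renin cells, 1.11% and 0.524%. Cycling cells, found by genes of DNA replication and mitosis, were 1.85% and 1.43%.

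Immune-like cells made up 0.927% (0.663 to 1.26) of the wild type and 14.7% (13.9 to 15.6) of the knockout library, and myeloid cells accounted for most of the gap. Macrophage-like cells were 4 and 664, or 0.0927% and 9.40% (8.73 to 10.1), and monocyte-like cells 5 and 237, or 0.116% and 3.35%. Neutrophil-like cells were 0 in wild type, a limit of 0.0695%, and 84 in knockout, or 1.19% (0.949 to 1.47). Lymphocytes differed far less, with T-like cells at 0.324% and 0.552% (ratio 1.70, 0.904 to 3.39) and B-like cells at 0.394% and 0.226% (ratio 0.575, 0.272 to 1.21). Unnamed cells were 0.973% of the wild type and 13.7% of the knockout library, so the named knockout shares are low by up to that amount. Both dissociation and the mitochondrial filter act on cell types unequally. Under a mitochondrial limit of 25% the principal-like ratio was 22.9 against 4.92, where a cluster of 110 wild type and 165 knockout cells with principal and distal convoluted markers went unnamed. The same limit gave an immune-like ratio of 8.29 against 15.9 and a thick ascending limb-like ratio of 3.74 against 1.03, and the endothelium-like ratio turned from 1.87 to 0.972. Clustering the libraries separately gave an immune-like ratio of 36.1 and a distal convoluted ratio of 2.37 against 0.980. Thinning to equal depth gave a principal-like ratio of 8.62, keeping doublets a cycling ratio of 1.53 against 0.771, and a coarser clustering an intercalated ratio of 0.529 against 0.959.

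**Figure D1:**
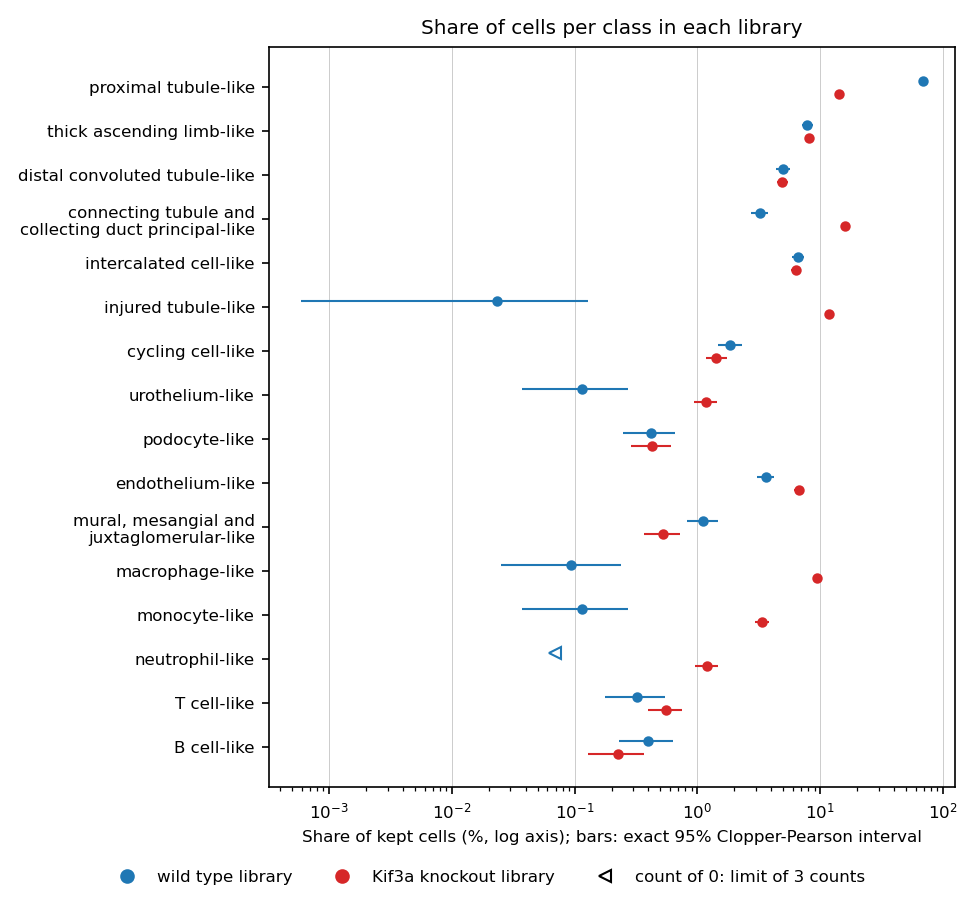
Share of kept cells per class in each library, in percent on a log axis, with exact 95% intervals as bars and an open triangle at the limit of 3 counts where no cell was found. Proximal tubule-like cells stand at 68.2% in wild type and 14.4% in knockout, while macrophage-like cells stand at 0.0927% and 9.40%.

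Within the classes, each library's cells mostly sat in clusters of their own, so the comparisons below set different clusters side by side. Wild type proximal tubule-like cells filled clusters 0, 1, 2, 9 and 13, and 833 of the 1015 knockout cells sat in cluster 11. Thick ascending limb-like cells were in cluster 4 in wild type and cluster 22 in knockout, distal convoluted tubule-like cells in clusters 3 and 16 against 16, and principal-like cells in cluster 6 against clusters 6 and 23. The markers Pvalb and Trpm6 passed in cluster 3 but not in cluster 16. Distal convoluted differences may therefore follow the kind of cell as well as the library, which was not tested. Intercalated-like cells (clusters 5 and 8) and endothelium-like cells (clusters 7 and 14) shared their clusters, though in different proportions. Cluster 5, where the marker Slc4a1 passed, held 123 wild type and 307 knockout cells. Cluster 8, where Slc26a4 passed, held 163 and 142. Endothelium-like cells were 58 and 216 in cluster 7 and 97 and 258 in cluster 14. Part of the intercalated-like differences, that of Kif3a included, may follow this mix. Lcn2, a gene of injury and acute inflammation, was among the 10 leading genes of clusters 22 and 23 as well as of 24 and of the cycling cluster 18, so part of the difference within the limb and the collecting duct was built in by the names. Gene lists were compared with 10000 random lists of like expression, and the percentile given for each list is a description of these libraries only. Each class had its own shift of the median gene, and list medians and counts of higher or lower members below are given relative to it. Medians under alternatives are given before its subtraction. In log2 units that shift was 0.24 in proximal tubule, 0.46 in thick ascending limb, 0.45 in distal convoluted tubule, 0.02 in principal, 0.27 in intercalated and 0.03 in endothelium-like cells.

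**Figure D2:**
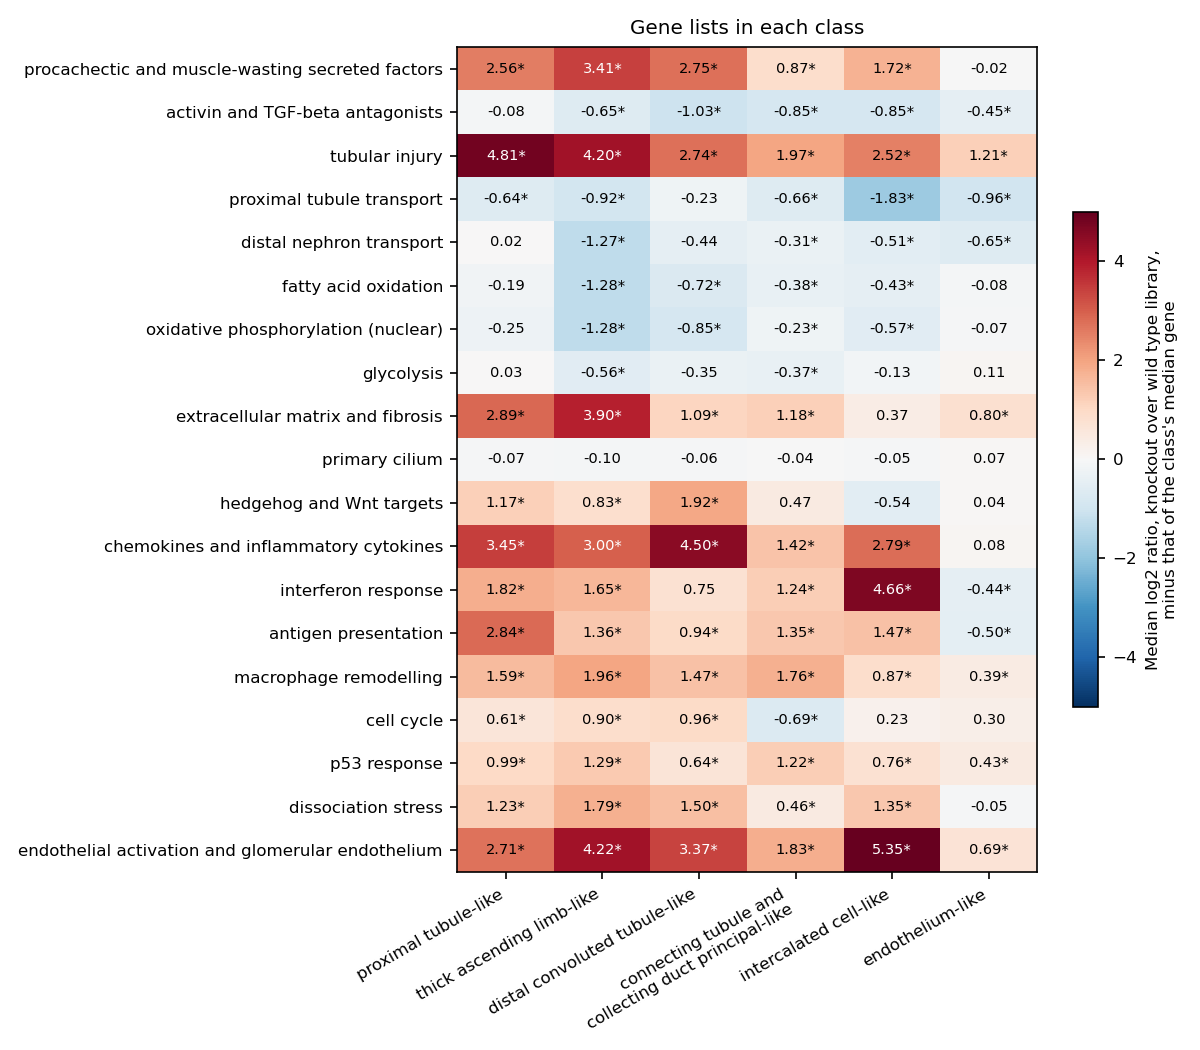
Median log2 ratio of each gene list in each class, knockout over wild type, minus that of the class's median gene, with a star where the median lies outside the central 95% of matched random lists. The tubular injury list is higher in every class, from 4.81 in proximal tubule-like to 1.21 in endothelium-like cells, while the primary cilium list stays near 0 in all of them.

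In proximal tubule-like cells of the knockout library the injury, matrix and antigen presentation lists stood higher and the proximal transport list lower. Cp, which encodes the copper-carrying ferroxidase ceruloplasmin, stood at 0.197 CPM in wild type and 55.6 in knockout (log2 ratio 8.02, 7.01 to 9.59). Sparc, a matricellular protein, was at 9.47 and 685 (6.18, 6.01 to 6.35), complement C3 at 3.09 and 157 (5.66, 5.37 to 5.98), and the fibrinogen chains Fgg and Fga at 5.82 and 226 and at 4.70 and 113. Cd74, the invariant chain of MHC class II, was at 12.6 and 519 (log2 ratio 5.37, 5.22 to 5.52), and H2-Ab1, a class II chain, at 8.94 and 232. Gdf15, a stress hormone that curbs appetite, was at 8.81 and 167 (4.24, 4.06 to 4.43), the cell cycle inhibitor Cdkn1a at 5.69 and 104, and the fatty acid hydroxylase Cyp4a14 at 12.4 and 249.9. The lowest gene was Slco1a1, an organic anion transporter, at 78.0 and 0.565 (log2 ratio -6.99, -8.56 to -5.98). Acsm3, a medium-chain acyl-CoA synthetase, was at 98.0 and 1.51 (-5.98, -6.83 to -5.32), lipoprotein lipase Lpl at 98.7 and 4.43, and the fatty acid carrier Cd36 at 50.9 and 4.05. Slc22a30 at 144 and 8.95, Slc22a28 at 87.3 and 8.76, Cyp4b1 at 329 and 35.6 and Ces1f at 198 and 21.9 were also lower. Most of them have close relatives in the genome, which makes their counts less certain. Slco1a1 and Acsm3 were found almost only in wild type clusters 2 and 13, and against clusters 0 and 9, at 0.569 and 1.29, their difference vanished in an alternative added after the data were seen. Slc22a30 at 49.6, Slc22a28 at 63.6 and Cyp4b1 at 53.5 in clusters 0 and 9 were higher there than in knockout cells.

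The tubular injury list had a median log2 ratio of 4.81 above the median gene in these cells (percentile 100.0, 22 of 23 genes higher). Its largest ratios were those of Cp, Anxa3, Anxa2 (0.263 and 47.3) and the actin-sequestering Tmsb10 (1.55 and 223). Antigen presentation stood at 2.84 (percentile 100.0, 13 of 13 higher). Extracellular matrix and fibrosis was at 2.89 (percentile 100.0, 9 of 9), with Vim at 0.263 and 15.9 and Timp1 at least 59.2-fold higher. The p53 response was at 0.99 (percentile 100.0, 13 of 15), with Phlda3 at 0.822 and 19.3. Interferon response was at 1.82 (percentile 99.99, 8 of 10) with Ifitm3 at 1.18 and 17.8. Hedgehog and Wnt targets were at 1.17 (percentile 99.89, 3 of 6), with the hedgehog ligand Ihh at 4.47 and 33.3 and Myc at 1.77 and 12.2. Secreted factors linked to wasting were at 2.56 (percentile 100.0, 13 of 16), with osteopontin, encoded by Spp1, at 1027 and 15450 and the growth factor Gdf11 at 0.263 and 8.76. Proximal tubule transport was lower at -0.64 (percentile 0.02, 11 of 18 lower), beyond Slco1a1 with Slc17a3 at 186 and 76.9, Slc7a8 at 189 and 86.7 and Slc22a8 at 322 and 162. Fatty acid oxidation (-0.19, percentile 15.7), oxidative phosphorylation (-0.25, percentile 16.1) and the primary cilium (-0.07, percentile 14.5) did not stand out. Within them, Acat1 of ketone metabolism was at 403 and 132 and the cilium gene Arl13b at 5.88 and 11.0. These cells held a median of 27.97% mitochondrial UMIs in wild type and 20.0% in knockout. Dissociation stress was at 1.23 (percentile 100.0, 12 of 17 higher). Lcn2, Clu, Krt19, S100a6 and Cd24a lay at 0.868 to 1.24 times the level of free RNA in the knockout library and are not read as expressed here, though they are among the 22 injury genes counted as higher. Lcn2 is also among the 13 secreted factors counted as higher, as are Ctgf and Ccl2 at 1.68 and 1.95 times that level. The hedgehog and Wnt result ended (percentile 21.1) with members of at least 100 UMIs, and the transport result (percentile 3.39) under a mitochondrial limit of 25%. In cells with few dissociation transcripts, an alternative added after the data were seen, the interferon (percentile 95.05) and hedgehog and Wnt (percentile 29.7) results ended.

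**Figure D3:**
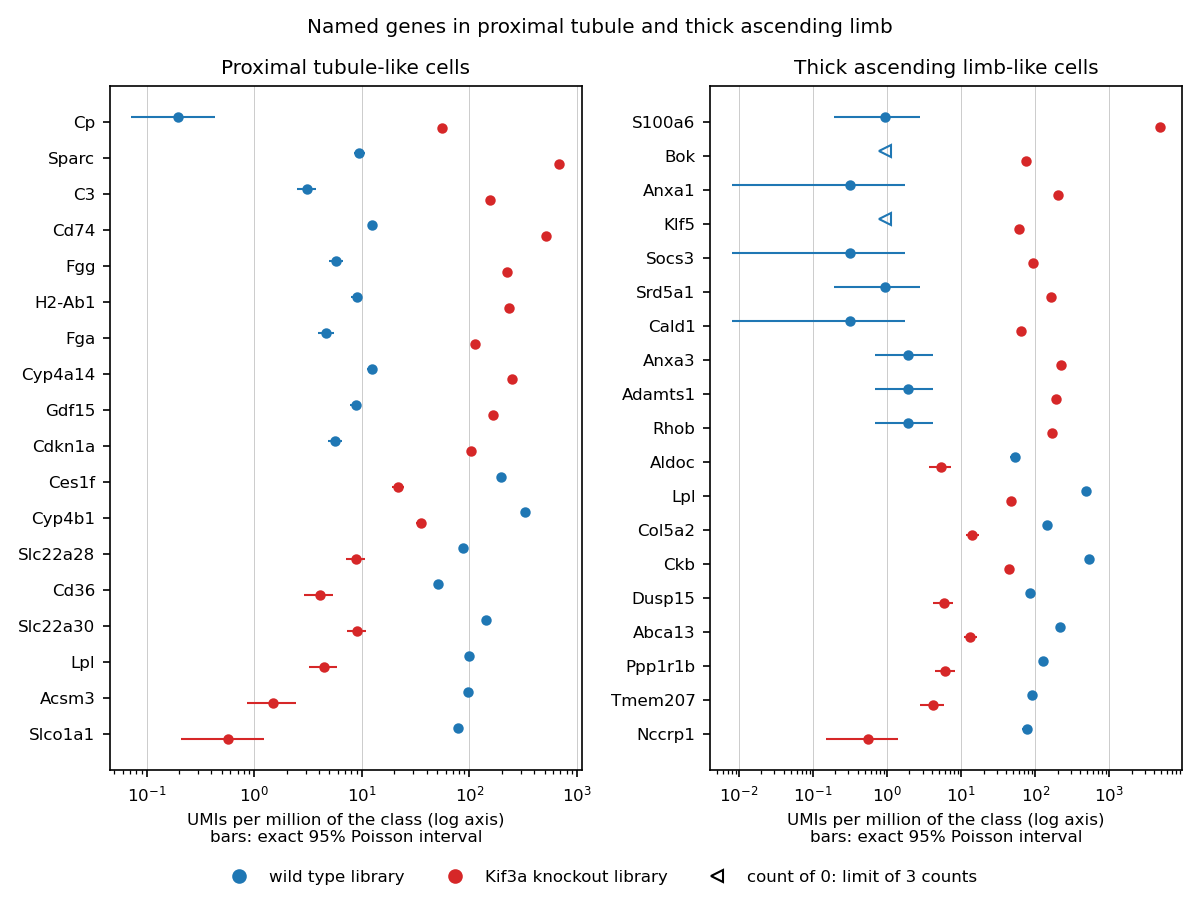
Level in CPM of the class in each library (log axis) for named genes in proximal tubule-like and thick ascending limb-like cells, with exact 95% Poisson intervals as bars and open triangles at the limit of 3 counts where no UMI was found. Sparc stands at 9.47 in wild type and 685 in knockout, S100a6 at 0.940 and 4859, and Slco1a1 at 78.0 and 0.565.

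In thick ascending limb-like cells of the knockout library the injury, matrix and secreted factor lists stood higher, and the oxidative phosphorylation, fatty acid oxidation and distal transport lists lower. S100a6, a calcium-binding protein of reactive epithelium, was found at 0.940 CPM in wild type, from 3 UMIs, and at 4859 in knockout (log2 ratio 12.11, 10.79 to 14.61). Annexin Anxa1 was at 0.313 and 201 (8.74, 6.84 to 14.63), from 1 wild type UMI, and Anxa3 at 1.88 and 223 (6.77, 5.76 to 8.34). Socs3, which restrains cytokine signalling, was at 0.313 and 94.1 (log2 ratio 7.65, 5.75 to 13.54), and the steroid reductase Srd5a1 at 0.940 and 165 (7.24, 5.91 to 9.74). Bok, a BCL2 family member, and the epithelial transcription factor Klf5 had no wild type UMI and were at least 78.6-fold and 63.6-fold higher. The protease Adamts1 was at 1.88 and 193 and the GTPase Rhob at 1.88 and 168. Lower genes included Nccrp1 at 76.2 and 0.553 (log2 ratio -6.94, -8.99 to -5.73), Tmem207 at 91.5 and 4.14, the phosphatase inhibitor Ppp1r1b at 129 and 6.08, Abca13 at 218 and 13.3, Dusp15 at 85.6 and 5.80 and Col5a2 at 146 and 14.1. Creatine kinase Ckb at 525 and 43.5 (-3.59, -3.77 to -3.42), Lpl at 485 and 47.5 and aldolase Aldoc at 53.9 and 5.25 were lower as well.

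Oxidative phosphorylation was lower in all 25 measured genes of its list (-1.28, percentile 0.0), with Sdha at 378 and 173, Uqcrfs1 at 573 and 268 and Cox7a2 at 1930 and 903. To a lesser degree this list was also lower in distal convoluted tubule-like cells (-0.85, percentile 0.02, 22 of 25 lower). The same held for intercalated-like (-0.57, percentile 0.02, 11 of 25) and principal-like cells (-0.23, percentile 0.7, 3 of 25). In the limb, fatty acid oxidation stood at -1.28 (percentile 0.0, 17 of 22 lower), with Acat1 at 405 and 115, Hadhb at 297 and 112 and Acadvl at 170 and 67.2. Glycolysis was at -0.56 (percentile 1.94, 8 of 16 lower), with Pfkm at 39.2 and 11.9 but lactate dehydrogenase Ldha at 97.48 and 301. On the CPM scale 3 of its genes were at least 1.5-fold lower and 3 higher. Distal nephron transport was at -1.27 (percentile 0.0, 13 of 17 lower), with the potassium channel Kcnj10 at 61.8 and 9.95 and klotho, encoded by Kl, at 159 and 36.8. The calcium binder S100g went the other way, at 37.9 and 352. The injury list was at 4.20 (percentile 100.0, 22 of 23 higher), with Krt19 at 0.940 and 348 (log2 ratio 8.31, 6.98 to 10.81). Extracellular matrix and fibrosis was at 3.90 (percentile 100.0, 10 of 11), with Fn1 at least 29.4-fold higher and Acta2 at 1.25 and 37.4. Macrophage remodelling was at 1.96 (percentile 100.0, 8 of 10), with the galectin Lgals3 at 97.48 and 1058. Secreted factors linked to wasting reached 3.41 (percentile 100.0, 14 of 16), with Ctgf, a matrix-inducing factor, at 2.51 and 186, Gdf15 at 1.88 and 125, Spp1 at 2537 and 40910 and the TWEAK gene Tnfsf12 at 0.627 and 19.1 (log2 ratio 4.61, 3.05 to 7.99). The dissociation stress list was at 1.79 (percentile 100.0, 17 of 19 higher), with Klf2 at 2.51 and 114 and Atf3 at 1.25 and 42.6. The median mitochondrial percent was 34.2 in wild type and 7.24 in knockout. Glycolysis came to percentile 3.76 with members of at least 1 UMI. Among cells with few dissociation transcripts, an alternative added after the data were seen that kept only 29 knockout cells, distal transport came to 0.07 (percentile 29.4) and glycolysis to percentile 13.3.

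In distal convoluted tubule-like cells of the knockout library the chemokine, injury and dissociation stress lists stood higher, while Kl and Defb1 were lower. Fgg and Adamts1 had no wild type UMI and were at least 62.7-fold and 35.5-fold higher. Sema3c, a guidance factor, was at 0.599 and 119 (log2 ratio 7.04, 5.14 to 12.93), the transcription factors Klf2 at 0.599 and 85.0 (6.56, 4.66 to 12.46) and Klf4 at 2.40 and 105 (5.28, 4.08 to 7.33), and Dcdc2a, a doublecortin family gene, at 3.60 and 134. Samd5 was at 0.599 and 65.3 (6.19, 4.28 to 12.08), and the actin-capping Capg at 1.20 and 78.4 (5.71, 4.17 to 9.08). Klotho, encoded by Kl, the coreceptor for FGF23, was at 1147 and 209.8 (log2 ratio -2.45, -2.57 to -2.33), and the antimicrobial Defb1 at 4715 and 948 (-2.31, -2.37 to -2.26). Lrrc52, a subunit of potassium channels, was at 50.4 and 2.18 (-4.46, -5.70 to -3.53), urocanase Uroc1 at 105 and 7.28, afamin Afm at 55.7 and 7.53, Gpx6 at 179 and 28.9, Ckb at 376 and 63.6, Lpl at 357 and 62.4 and Larp1b at 322 and 68.0.

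Chemokines and inflammatory cytokines stood at 4.50 in these cells (percentile 100.0, 7 of 7 higher), with Il34 and Cxcl10 at least 21.5-fold and 17.8-fold higher and Cx3cl1, a tether for monocytes, at 6.59 and 47.1. The injury list was at 2.74 (percentile 100.0, 17 of 18), with Lcn2 at least 1095-fold higher at 1969 CPM, Anxa2 at 4.20 and 136 and Tmsb10 at 30.0 and 541. Secreted factors linked to wasting were at 2.75 (percentile 100.0, 8 of 11), with Gdf15 at 0.599 and 85.0 (log2 ratio 6.56, 4.66 to 12.46), endothelin Edn1 at 1.80 and 29.4 (3.81, 2.45 to 6.33), Spp1 at 3059 and 31300 and the death ligand Tnfsf10 at 9.59 and 36.4. The list of activin and TGF-beta antagonists was lower at -1.03 (percentile 0.05, 7 of 9), with Igf1 at 41.4 and 3.16 and Bmp7 at 31.8 and 17.2, against Fstl1 at 7.79 and 21.1. Igf1 is a growth factor and Bmp7 a ligand of the TGF-beta family, so the list is not limited to antagonists. On the CPM scale 4 of these 9 were at least 1.5-fold lower and 2 higher. Fatty acid oxidation was at -0.72 (percentile 0.0, 14 of 22 lower), with Acsl1 at 112 and 32.5 and Acat1 at 364 and 171. On the CPM scale 8 of these 22 were at least 1.5-fold lower and 1 higher. Distal nephron transport was at -0.44 (percentile 2.97, 8 of 18 lower), with Klhl3, a regulator of the salt cotransporter, at 369.8 and 81.1 and Cldn19 at 5.99 and 119.9. Dissociation stress was at 1.5 (percentile 100.0, 13 of 18 higher), with Junb at 2.997 and 71.9, and the median mitochondrial percent was 36.2 and 13.5. Distal transport moved to percentile 0.05 with doublets kept, 0.21 with at least 1000 UMIs per cell and 1.54 with members of at least 100 UMIs.

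In principal-like cells of the knockout library the injury, p53 and interferon lists stood higher and the antagonist and cell cycle lists lower. Socs3, the interleukin 18 receptor gene Il18r1 and Anxa3 had no wild type UMI and were at least 59.6-fold, 34.8-fold and 34.2-fold higher. Ociad2 was at 1.92 and 190.3 (log2 ratio 6.31, 4.78 to 9.68), Dcdc2a at 1.92 and 146 (5.93, 4.40 to 9.30), and the p53 target Rprm at 1.92 and 82.6 (5.11, 3.57 to 8.48). Podoplanin, encoded by Pdpn, was at 3.83 and 114, the stem cell antigen Ly6a at 41.2 and 905 (4.44, 4.03 to 4.93), the sodium channel Scn8a at 3.83 and 73.7, and Adamts1 at 4.79 and 83.0. The calcium pump Atp2b2 was at 72.8 and 1.21 (-5.89, -6.70 to -5.19), acetylcholinesterase Ache at 69.9 and 1.51 (-5.51, -6.25 to -4.86), and the ammonium transporter Rhbg at 105 and 9.74. Ranbp3l at 82.4 and 9.80, Snn at 196 and 25.3, Smim5 at 208 and 28, Spock3 at 70.9 and 9.62, the linker histone Hist1h1c at 261 and 41.1, the muscle-type enzyme Pgam2 at 224 and 36.2 and Lyst at 166 and 29.3 were lower too.

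Their injury list stood at 1.97 (percentile 100.0, 14 of 17 higher), with S100a6 at 5.75 and 1036, Spp1 at 156 and 13880 and the chaperone Clu at 117 and 3681. The 829 knockout cells of cluster 24, also led by Aqp2, Fxyd4 and Hsd11b2, were named injured tubule-like and left out of this class. The naming may therefore have lowered this median. The p53 response was at 1.22 (percentile 100.0, 13 of 15), with Cdkn1a at 6.71 and 111 and Phlda3 at 1.92 and 45.6 (log2 ratio 4.25, 2.72 to 7.62). The p53 list was also higher in thick ascending limb-like (1.29, percentile 100.0, 11 of 15) and intercalated-like cells (0.76, percentile 99.99, 7 of 12). In distal convoluted tubule-like cells it was at 0.64 (percentile 99.68, 6 of 11 higher and 3 lower). Interferon response in principal-like cells was at 1.24 (percentile 99.99, 11 of 15), with Bst2 at 17.2 and 83.7 and Ifitm3 at 108 and 439. Secreted factors linked to wasting were at 0.87 (percentile 99.97, 6 of 11), with Tgfb2 at 8.62 and 36.7, Gdf15 at 85.3 and 298 and Tnfsf12 at 7.66 and 27.2. The list of activin and TGF-beta antagonists was at -0.85 (percentile 0.03, 6 of 10 lower). In it Fstl1 was at 148 and 61.8, Kl at 189 and 79.7 and the growth factor Igf1 at 15.3 and 3.57, while Grem1 was at least 3.16-fold higher. Cell cycle genes were at -0.69 (percentile 0.03, 9 of 16 lower), with the helicase subunits Mcm3 at 17.2 and 4.35 and Mcm5 at 10.5 and 3.45 and Tyms at 44.1 and 24.1. Glycolysis was at -0.37 (percentile 0.3, 5 of 15 lower), with the glucose transporter Slc2a1 at 254 and 117 and Eno1 at 508 and 297. Dissociation stress was at 0.46 (percentile 99.85, 7 of 19 higher). The median mitochondrial percent was 13.8 and 7.48 and the median depth 6750 and 10743 UMIs, so rare genes were seen more readily in the knockout cells. With members of at least 1 UMI the secreted factor median came to -0.05 (percentile 92.6) and the cell cycle list to percentile 4.01, and in cells with few dissociation transcripts, added after the data were seen, the latter came to percentile 6.47. The class totals were 1043914 UMIs in wild type and 16533861 in knockout. With 0.5 UMIs added to each sum, a member with few knockout UMIs and none in wild type gets a negative log2 ratio. The fall of the secreted factor median may come from this step.

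In intercalated-like cells of the knockout library the interferon and injury lists stood higher, while Igfbp5 was lower. Fgg and Socs3 had no wild type UMI and were at least 149.8-fold and 118.9-fold higher. The immunoglobulin carrier Pigr was at 0.627 and 65.8 (log2 ratio 6.39, 4.85 to 9.77), Tmem158 at 17.9 and 875, Rasl11a at 2.82 and 143, Klf4 at 1.88 and 73.9, Marcksl1 at 3.76 and 81.2 and Rhob at 4.07 and 57.4. Igfbp5, which binds insulin-like growth factors, was at 611 and 100.5 (-2.60, -2.76 to -2.45), Malrd1 at 125 and 23.3, the acyl-CoA thioesterase Acot3 at 121 and 26.4, Kctd12 at 135 and 30.2 and Gng11 at 175 and 41.0. Tbc1d24 at 86.8 and 21.4, the metalloreductase Steap2 at 72.0 and 18.6, the nuclear receptor Rorb at 50.7 and 13.1, synaptotagmin Syt7 at 59.8 and 16.2 and Sh3pxd2a at 80.8 and 24.3 were lower as well. Interferon response stood at 4.66 (percentile 100.0, 9 of 11 higher), with Oasl2 and Rsad2 at least 27.1-fold and 17.2-fold higher and Ifitm3 at 6.89 and 254 (log2 ratio 5.17, 4.60 to 5.89). Antigen presentation was at 1.47 (percentile 100.0, 9 of 11), with the immunoproteasome subunit Psmb8 at 2.19 and 43.4 and H2-D1 at 83.6 and 281. The injury list was at 2.52 (percentile 100.0, 17 of 18), with Krt19 at 5.33 and 77.4 and Clu at 104 and 1292. In knockout Lcn2 lay at 1.02 and S100a6 at 1.70 times the level of free RNA, and both are among these 17. Secreted factors linked to wasting were at 1.72 (percentile 100.0, 8 of 12), with Edn1 at 0.313 and 23.1 (5.63, 3.69 to 11.52) and Tnfsf10 at 1.57 and 15.2. Of the 12, Lcn2, Gdf15 and Ctgf lay at only 1.02, 1.46 and 1.86 times the level of free RNA in knockout. The antagonist list was at -0.85 (percentile 0.03, 5 of 8 lower), with Bmp7, itself a ligand of the TGF-beta family, at 34.8 and 11.4. Fatty acid oxidation was at -0.43 (percentile 0.06, 8 of 22 lower), with Acat1 at 304 and 168. Dissociation stress was at 1.35 (percentile 100.0, 13 of 18 higher), with Atf3 at 2.19 and 37.2. The median mitochondrial percent was 24.9 and 10.4. The antagonist result ended (percentile 6.37) with members of at least 100 UMIs. In cells with few dissociation transcripts, an alternative added after the data were seen, so did fatty acid oxidation (percentile 20.6), antigen presentation (percentile 82.7) and, again, antagonists (percentile 6.66).

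In endothelium-like cells of the knockout library the endothelial activation and matrix lists stood higher and the interferon list lower. Apelin, encoded by Apln, a tip cell factor, was at 1.54 and 62.1 CPM (log2 ratio 4.75, 2.82 to 10.65), its receptor Aplnr at 10.8 and 76.3 (2.73, 1.74 to 4.16) and the tip cell proteoglycan Esm1 at 21.6 and 219 (3.30, 2.58 to 4.23). Pleiotrophin, encoded by Ptn, was at 10.8 and 166, Ctgf at 35.5 and 212, Cyr61 at 12.3 and 72.9, Trp53i11 at 9.25 and 63.8, Slc45a4 at 12.3 and 64.9 and Clca3a1 at 1.54 and 68.9 (4.90, 2.98 to 10.80). AA467197 had no wild type UMI and was at least 11.4-fold higher. Glycam1, a mucin-like ligand of high endothelium, was at 751 in wild type and absent from knockout, at least 439.5-fold lower, and Serpina1b was at 116 and 0.569 (-7.09, -12.99 to -5.14). Ifi27l2a, an interferon-induced gene, was at 207 and 19.4 (-3.40, -4.00 to -2.86), Krt80 at 81.7 and 10.8 and Serpinb1a at 77.1 and 15.9. H2-Q7 at 100.2 and 21.1, the prostaglandin-degrading Hpgd at 149 and 42.7, the phosphatase Ptprr at 276 and 79.1, Gadd45b at 83.2 and 25.05 and Lpin2 at 86.3 and 26.2 were lower too. Endothelial activation and glomerular endothelium stood at 0.69 (percentile 100.0, 9 of 17 higher), with Angpt2, a destabiliser of vessels, at 6.17 and 47.8. Extracellular matrix and fibrosis was at 0.80 (percentile 100.0, 11 of 17), with Col4a1 at 484 and 1335, Col4a2 at 317 and 921, Bgn at 49.3 and 152 and Acta2 at 27.7 and 101. Interferon response was at -0.44 (percentile 0.05, 6 of 14 lower), with Irf7 at 131 and 60.9. Antigen presentation was at -0.50 (percentile 0.22, 3 of 9 lower), with H2-K1 at 1256 and 684 and Psmb9 at 116 and 64.9 against Cd74 at 10.8 and 38.1. The injury list was at 1.21 (percentile 100.0, 12 of 17 higher), with Tmsb10 at 151 and 627. Secreted factors linked to wasting (-0.02, percentile 39.0), dissociation stress (-0.05, percentile 29.3) and cell cycle (0.30, percentile 93.6) did not stand out, apart from single members such as Egr1 at 10.8 and 52.4 and Tyms at 13.9 and 51.8. These cells had little mitochondrial RNA, with medians of 5.86% and 4.01%, but free RNA made up 7.43% and 4.90% of their UMIs. In knockout Lcn2 and Spp1 lay below its level and Krt8, Krt18, Krt19, Cryab and Clu at 1.07 to 1.69 times it, and these 7 are among the 12 injury genes counted as higher. Antigen presentation turned to a median of 1.03 when doublets were kept, and the activation and matrix lists came to percentile 96.5 with members of at least 100 UMIs and 97.4 as a mean over cells.

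Over all kept cells, most secreted factors linked to wasting were higher in the knockout library. The largest differences were in factors whose largest knockout source was injured tubule-like or myeloid cells. The median of the list was 1.90 above that of the median gene, with 22 of 27 measured factors at least 1.5-fold higher and 5 lower relative to it, or 22 and 2 on the CPM scale. Lcn2, which encodes lipocalin 2, an appetite-curbing iron carrier, was at 4.64 (4.01 to 5.33) and 4065 (4051 to 4079) CPM, and injured tubule-like cells gave 47.9% of the knockout UMIs. Lcn2 helps to name that class and leads its cluster, so this source is partly built in by the name. Spp1 was at 1318 and 16840 (12.8-fold, 12.7 to 12.9), with thick ascending limb-like cells as the largest source at 22.2%. Gdf15 was at 10.4 and 194 (18.7-fold, 17.0 to 20.6), with principal-like cells at 32.2%. The monocyte attractant Ccl2 was at 0.141 and 28.1 (184-fold, 91.3 to 543), with 47.2% from macrophage-like cells. Interleukin 1 beta, encoded by Il1b, was at 0.165 and 8.27 (46.9-fold, 24.2 to 125), with 41.9% from monocyte-like cells. Il1a was found in 1 and 120 UMIs (43.1-fold, 11.4 to 2567), Tnf in 1 and 116 (41.7-fold, 11.0 to 2482), and the leukaemia inhibitory factor gene Lif in 2 and 155 (33.4-fold, 11.3 to 347), while oncostatin M, encoded by Osm, was at least 10.7-fold higher. Tgfb2 was at 3.49 and 34.4, with injured tubule-like cells giving 46.7%, Tgfb1 at 3.39 and 16.6, and Tgfb3 at 0.283 and 1.33. Ctgf stood at 4.61 and 54.6, Edn1 at 2.78 and 15.8, Tnfsf10 at 9.35 and 39.1, Tnfsf12 at 10.5 and 28.1, Clcf1 at 1.06 and 9.74 and Gdf11 at 1.06 and 3.97. Il11 and Pthlh stood 2.99-fold (1.58 to 6.84) and 3.71-fold (1.99 to 8.41) higher on few UMIs. Without cluster 28, which carried genes of fat cells and of connective tissue and was left out after the data were seen, Pthlh came to 1.79-fold (0.895 to 4.20).

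Activin A transcripts came mostly from outside the tubule in these libraries. Inhba, which encodes its subunit, had 11 UMIs in wild type, all from mural-like cells, and 63 in knockout, of which 6 were from tubular epithelium, or 0.259 (0.129 to 0.464) and 0.797 (0.612 to 1.02) CPM. Of the knockout UMIs, 34.9% came from mural-like cells and 42.9% from unnamed cluster 28, a knockout cluster with genes of fat cells and of connective tissue. Its closest marker type was fibroblast, with 4 of 9 markers, and no cluster was named as fibroblast in either library. Leaving it out may therefore remove kidney fibroblasts as well as fat. Without cluster 28, left out after the data were seen, Inhba was at 0.259 and 0.462 CPM (1.73-fold, 0.888 to 3.88), an interval that includes 1. Mural-like levels of 56.4 and 106 CPM rest on so few counts that they are not told apart. Inhbb, the subunit of activin B, was at 0.235 and 2.02 (8.21-fold, 4.55 to 18.3), with thick ascending limb-like cells as the largest source at 46.9% of the knockout UMIs. Among members of the antagonist list, follistatin, encoded by Fst, had 2 and 229 UMIs (49.3-fold, 16.8 to 511), and Grem1 was at least 40.3-fold higher. By contrast, Kl was at 299 and 67.7 (4.42-fold lower, 4.28 to 4.57) and Chrd at 2.80 and 0.797 (3.50-fold lower, 2.57 to 4.85). Renin, encoded by Ren1, was 5.61-fold lower (4.91 to 6.44) at 20.5 and 3.64 and came almost wholly from mural-like cells in both libraries, a class that it helps to name. Within mural-like cells the difference was smaller, at 4431 and 1344 CPM, and the share of these cells was lower too. The inflammatory factor Mif was 1.86-fold lower (1.83 to 1.89) at 882 and 474, Agt 1.40-fold and Adm 1.41-fold lower, and Angptl4 stood level at 8.05 and 7.96. Proximal tubule-like cells were the largest wild type source of Agt, Angptl4, Mif, Chrd and Kl. Within them Agt (8.88 and 30.4) and Angptl4 (10.7 and 38.5) were higher in knockout. Mif (899.8 and 1084) differed by about the shift of the class's median gene, a log2 ratio of 0.24. Chrd was near level there (3.68 and 3.39) and Kl was lower (315 and 123). These whole-library levels follow the mix of cells as much as the level within a class, and the mix differed as described.

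**Figure D4:**
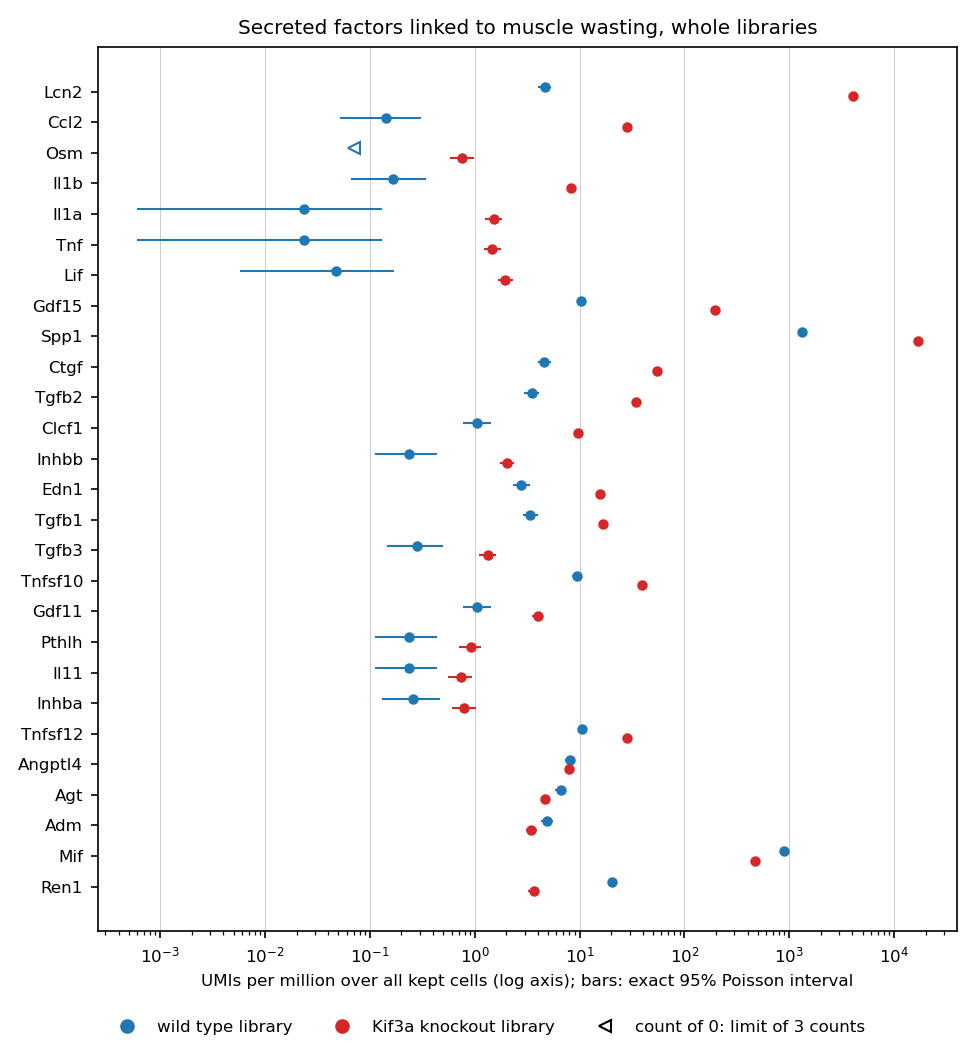
Level in CPM over all kept cells (log axis) of each secreted factor linked to muscle wasting in the 2 libraries, with exact 95% Poisson intervals as bars and an open triangle at the limit of 3 counts where no UMI was found. Lcn2 stands at 4.64 in wild type and 4065 in knockout, Inhba at 0.259 and 0.797, and Ren1 at 20.5 and 3.64.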

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

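Of the tests on the injury list, the one on mitochondrial percent was chosen only after the result was seen and the one on dissociation used a set of cells added after the data were seen, while all tests on the immune-like share were chosen only after the result was seen.

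The tubular injury list was higher in the knockout library in every tubule class. Free RNA from the injured cells was tested by subtraction. The list stayed above the central 95% of random lists in 5 of 5 tubule classes. Medians here and below are before subtraction of the median gene. With free RNA subtracted they were 5.40 against 5.05 in proximal tubule and 5.02 against 4.66 in thick ascending limb. The rest were 2.98 against 3.19 in distal convoluted tubule, 1.97 against 1.99 in principal and 2.77 against 2.79 in intercalated-like cells. A member at the level of free RNA can lose its counts and drop out without lowering the median. In knockout Lcn2, Clu, Krt19 and S100a6 in proximal tubule and Lcn2 in intercalated-like cells lay at 0.868 to 1.02 times that level. The medians there may cover only members that remained. In thick ascending limb, distal convoluted tubule and principal-like cells every measured member lay at 3.188 times that level or more. There the test argues against free RNA as the whole cause. Immediate early stress of the dissociation was tested in cells at or under the wild type median share of dissociation transcripts, and the list stayed high in 5 of 5 classes. Its median there was lower in thick ascending limb-like (2.79 against 4.66), distal convoluted tubule-like (1.65 against 3.19), intercalated-like (1.76 against 2.79) and proximal tubule-like cells (4.17 against 5.05), and near level in principal-like cells (1.93 against 1.99). Such stress may thus add to the difference, and the test cannot exclude it as the whole cause. The cut lay at 0.0333% to 0.139% of a cell's UMIs across the tubule classes, where few counts decide which cells pass. Only 29 of 573 knockout thick ascending limb-like cells did. The higher mitochondrial percent of the wild type cells was tested in cells matched on that percent, and 5 of 5 classes stayed high. The matched medians were 4.80 in proximal tubule, 2.73 in thick ascending limb, 2.41 in distal convoluted tubule, 1.53 in principal and 2.51 in intercalated-like cells, from 1015 to 104 cells per library. Different handling of the 2 libraries, whose barcodes had median mitochondrial percents of 39.0 and 8.18, goes with genotype and stays open. So do a response of the epithelium to the loss of Kif3a and a difference between the mice used.

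The immune-like share was 15.9 times higher in the knockout library. Fewer proximal tubule cells would raise all other types alike, but the highest upper bound among endothelium-like, mural-like and podocyte-like cells was 2.255, below the immune-like lower bound of 11.6. Thick ascending limb-like (1.03), distal convoluted tubule-like (0.980) and intercalated-like cells (0.959) were near level as well. Principal-like cells were higher by 4.92 (4.12 to 5.91) and urothelium-like cells by 10.1 (4.18 to 32.05), whose interval overlaps the immune-like one, so the types did not move alike. The mitochondrial filter, which removed more wild type cells, was tested by scoring all barcodes before it for immune markers at 0.5% or more of their non-mitochondrial UMIs. That gave 172 of 6938 wild type and 1306 of 7950 knockout barcodes, of which 122 and 122 had been removed for mitochondrial UMIs, and a ratio of 6.63 (5.65 to 7.81). With 6.63 before the filter against 15.9 after it, the filter may enlarge the ratio but is not its whole cause, though score and names pick cells differently. The removed barcodes had medians of only 351.5 and 269 non-mitochondrial UMIs in wild type and knockout. At that depth few marker UMIs are enough to pass the score. A stricter limit of 25% gave 8.29, which is lower as well and so does not speak for such an enlargement. More blood left in the knockout kidney would raise lymphocytes with myeloid cells, but the highest upper bound of B-like and T-like cells was 3.394 against a lowest lower bound of 12.2 for macrophage-like and monocyte-like cells. Inflammation of the knockout kidney remains a hypothesis that 1 library per genotype leaves untested.

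Some lists pointed in different directions in different classes. Before subtraction of the median gene, antigen presentation had a median log2 ratio of 3.08 in proximal tubule-like and -0.47 in endothelium-like cells, and interferon response 4.93 in intercalated-like and -0.42 in endothelium-like cells. Cell cycle genes were at 1.41 in distal convoluted tubule-like and -0.68 in principal-like cells. These pairs are listed because the medians lie on opposite sides of the random lists, and the difference was not tested. Antigen presentation in endothelium-like cells also turned with doublets kept, to 1.03.

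Part of the knockout library was left without a name. Cluster 10 held 7.10% of knockout cells (0.417% in wild type) at a median depth of 913 UMIs, and principal and injured tubule markers led it in equal number, 2 each. Cluster 25 held 4.23% (0.510% in wild type), with collecting duct genes of both principal and intercalated kinds at a median of 26177 UMIs. Cluster 12, with 1.46% (0.0463%), and cluster 28, with 0.906% (none, a limit of 0.0695%), had leading genes that are mostly outside the marker lists. Cluster 12 stayed unnamed because another type had as many markers among its 10 leading genes as its closest type. That closest type was parietal epithelium, with 4 of 5 markers passing. Genes of the unnamed clusters were not compared between libraries, because too few wild type cells were there.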

How the results depend on the processing

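The settings with cells of few dissociation transcripts and with selected wild type clusters were chosen only after the results were seen. No paired analysis was possible because each genotype has 1 library.

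With a mitochondrial limit of 25% the principal-like share ratio was 22.9, after a cluster of 110 wild type and 165 knockout cells with principal and distal convoluted markers went unnamed. The proximal tubule-like ratio was 0.162 and the immune-like 8.29, and the endothelium-like reversed to 0.972. The log2 ratio of Kif3a reversed to -0.0902 in the tubular epithelium and -0.19 in all cells. Principal-like, distal convoluted and thick ascending limb-like cells gave no class comparison there. Separate clustering gave 3.54 for principal-like, 0.251 for proximal tubule-like and 36.1 for immune-like cells. Resolution 2 gave 6.84 for principal-like, resolution 0.5 gave 0.230 for proximal tubule-like, and thinning gave 8.62 for principal-like cells, leaving out 310 wild type and 549 knockout cells.

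Kif3a in tubular epithelium and all cells reversed to -0.27 and -0.32 under trimmed means, -0.27 and -0.33 under median-of-ratios, and -0.0683 and -0.0881 without mitochondrial and abundant genes. A mean over cells gave 0.0361 in the epithelium.

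At 200 UMIs or more, 4 of 20 named genes remained in endothelium-like cells, 14 in principal-like and 17 to 20 in the rest, all with the same sign. Under the other settings chosen beforehand that gave a class comparison all 20 kept it, while the clustering and thinning settings were run for shares only. Against wild type clusters 0 and 9 the number was 17 of 20 in proximal tubule-like cells, and in cells with few dissociation transcripts 18 in distal convoluted and 19 in intercalated-like cells. Depth limits the rest, since the wild type library gave 1 injured tubule-like, 4 macrophage-like and 5 monocyte-like cells and 11 UMIs of Inhba, so these ratios are known only within their wide intervals.

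Of 51 list results, 51 held under each scaling and with free RNA subtracted, 50 at 1000 UMIs, 49 as a mean over cells, 48 with doublets, 47 and 45 with other member limits, and 25 of 27 at 25%. Medians here are before subtraction of the median gene. Secreted factors in principal-like cells came to -0.0495 with members of 1 UMI, and antigen presentation in endothelium-like cells reversed to 1.03 with doublets. In cells with few dissociation transcripts 34 of 49 held and 13 ended. For dissociation stress, in all 5 tubule classes, that was built in by the choice of cells. The other 8 were hedgehog and Wnt and interferon in proximal tubule, distal transport and glycolysis in thick ascending limb, cell cycle in principal, and antagonists, fatty acid oxidation and antigen presentation in intercalated-like cells. Secreted factors in endothelium-like cells reached 0.74 and fatty acid oxidation in proximal tubule-like cells 0.34, both above the random lists. The cause was not tested.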

Other observations

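The tests on androgen action and on a general loss were chosen only after the result was seen, and the test on the segment was set before its result but on clusters picked after the data were seen. Cluster 28, found only in the knockout library with 64 cells, carried genes of fat cells and of connective tissue. The fatty acid binder Fabp4 stood at 34450 CPM, the complement factor Cfd at 26520, Car3 at 9787, resistin (Retn) at 3130, adiponectin (Adipoq) at 1517, Plin1 at 352 and Pparg at 190.6, beside the collagen gene Col3a1 at 2026. Neither fat around the kidney taken along at dissection nor fibroblasts of the kidney itself were ruled out. Cluster 12 had 103 knockout cells with the nephron factor Pax8 at 253 CPM, Akap12 at 1340, Cp at 964, C3 at 545, Vcam1 at 391, Ccl2 at 225, the tight junction gene Cldn1 at 161 and follistatin (Fst) at 73.0.

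Over all kept cells several myeloid chemokines had no wild type UMI and were at least 386-fold (Ccl12), 258-fold (Ccl7), 132-fold (Ccl8) and 113-fold (Cxcl2) higher in knockout. The growth factors of macrophages Csf1 (1.44 and 31.1 CPM) and Il34 (3.34 and 49.5) were higher as well, while Cxcl12, which is made by stroma and vessels, was at 15.5 and 8.32. Among genes of macrophages, Mrc1 was at 0.118 and 28.3, Trem2 at 0.0942 and 16.4 and Arg1, from 2 wild type UMIs, at 0.0471 and 11.1 (log2 ratio 7.56, 6.03 to 10.93).

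Genes that are male-biased in the mouse proximal tubule were lower in knockout proximal tubule-like cells, with a median log2 ratio of -3.31 and 11 of 11 genes lower, though both libraries expressed Y-linked genes (Ddx3y 54.0 and 49.8 CPM). Medians here are before subtraction of the median gene. Loss of the segment that expresses them was tested against wild type clusters 0 and 9, and there the median was -0.0586 (percentile 6.07), with 4 of 10 genes lower and 2 higher, against -4.56 for clusters 2 and 13. That comparison decides nothing, since within the wild type library the list already stood at -3.98 in clusters 0 and 9 over clusters 2 and 13. Kap, an androgen-regulated gene that leads clusters 2 and 13 and so helped to define them, was at 249 CPM in clusters 0 and 9, 48950 in clusters 2 and 13 and 1029 in knockout. Less androgen action in the knockout mouse could not be told from this, since the female-biased list had a median of 1.98 with 3 of 6 genes higher and 2 lower, and the rule for this test was tightened after its value had been seen. Against clusters 0 and 9 the same list stood at 5.45 (percentile 100.0) with 3 of 5 genes higher and 0 lower. A general loss of abundant proximal transcripts was tested with the transport list, which stood 2.90 above the male-biased list. That decides nothing either, since the male-biased list was added after the data were seen and holds 5 of the 10 lowest named genes of the class. A general loss, fewer cells of that segment and less androgen action all stay open.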
